A study of Mus musculus with 6 samples.

How the data were processed

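RNA from LSK cells of mouse bone marrow was sequenced from 6 mice, 1 library per mouse. LSK cells are lineage-negative, Sca-1-positive, c-Kit-positive cells, the fraction that holds stem cells and multipotent progenitors. Per the labels, 3 mice were bcat(ex3)osb animals, in which β-catenin signalling was constitutively active in osteoblasts, and 3 were wild-type (WT) littermates. RNA was extracted with the AllPrep kit, and libraries were made with the Illumina TruSeq Stranded Total RNA kit with KAPA HiFi for the last PCR step, per the labels' protocols.

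Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5.2b and featureCounts 1.5.0-p3 were used with the mouse build mm10. The strand setting, the treatment of reads that map to several places and the gene annotation are not given in the sources used here. The authors deposited whole-number counts per gene, without normalization, for each library. They also deposited a table per library with the gene length in bases, the same counts and FPKM. Each deposited FPKM value equalled the count scaled by gene length and the library's total within 0.005, the rounding of the table. Genes with near-identical relatives, such as histone, ribosomal protein, Ly6, Ifitm, mast cell protease and major histocompatibility genes, are uncertain, since the counting of shared reads is not stated. The same holds for genes that overlap another gene on either strand.

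The counts were analysed as deposited. Genes were kept with edgeR's filterByExpr by genotype (minimum count 10, minimum total count 15), which left 12653 of 23420 genes. Differences between genotypes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, a quasi-likelihood fit with genotype as the only term, and the two-sided F test. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are mutant over WT, and their standard errors (SE) were derived from the F statistic. Levels are CPM, that is counts relative to the TMM-scaled library size, given as mean ± SD. For plots and list medians per mouse, log2 CPM was computed with a prior count of 1.

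Before the data were examined, 37 gene lists were written from general knowledge. They cover lineages, pathways, cell states, metabolism, RNA quality and other cell types that the sorted fraction could hold. Lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 35 lists tested. The mitochondrially encoded list had 0 genes in the table and the sex-linked list had 1 tested gene, so these went untested. Each list was also tested by camera with an estimated correlation and by fry, and single genes were adjusted over the list alone.

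The genes named in the text follow a rule written before the data were examined. Since no gene passed the threshold over all genes, the 5 smallest unadjusted p-values per direction were named. Sex-linked genes, unnamed predicted genes, and immunoglobulin and T cell receptor segments were left out. From each list, up to 4 tested members with the smallest unadjusted p were added, and Ctnnb1, Kit, Ly6a, Jag1, Notch1, Hes1, Axin2, Myc and the sex-linked genes always. Some genes that this rule names are not reported here. Mpo, Elane, Prtn3, Ctsg, Ms4a3, Irf8, Gfi1, Csf3r, Isg15, Irf7, Cd74, H2-Aa, Cd79a, Ebf1, Igll1, Vpreb1, Blnk, Pou2af1, Tpsb2, Cma1, Jun, Ier2, S100a8, Mt1 and Gria2 were chosen after their values were seen. Rag1, Rag2, Il7r, Dntt, Nrarp and Gata3 were also chosen then. Coordinates are 1-based, from a RefSeq gene table on GRCm38.p6, the assembly that mm10 also names, in which 11733 of the 12653 tested symbols matched.

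The procedure was tested on simulated data: counts for the 12653 genes were drawn from the real means and library sizes, with 200 genes changed, in 5 runs of bcat(ex3)osb against WT. Of the changed genes, 7.50% of those set to a 2-fold change and 68.9% of those set to a 4-fold change were called, and 5.81% of calls were false. In 20 runs camera called the list shifted by 1 log2 unit 20 times, and 4 of 680 tests of unshifted lists. Simulated genes were independent of each other, unlike real ones. The simulated libraries also lacked shared differences, such as the trend with gene length in the real libraries. These rates therefore may not hold for the real data.

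Total counts were between 15431235 and 19956774 per library. A gene with 0 counts in all 3 libraries of a group was bounded by a floor of 3 counts per library. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The alternatives tried were other scalings (RLE and upper-quartile), DESeq2 1.42.0, limma-voom, other filters on low counts, limma on log2 of the deposited FPKM plus 1 or 0.1, the mouse number as a block, a threshold of 0.10, a robust fit and leaving out each mouse. Added after the data were seen were sex as a covariate, the 4 female mice only, and the removal of each library's trend with gene length and GC content. GC content came from the longest annotated GENCODE transcript of each symbol and was known for 93.9% of tested genes. No labelled batch was given.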

Results

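The series measured gene expression in LSK cells, the bone marrow fraction that holds haematopoietic stem cells and multipotent progenitors, from 3 bcat(ex3)osb mice and 3 WT littermates. In the bcat(ex3)osb mice (mutant mice below) β-catenin signalling was constitutively active in osteoblasts, the bone-forming cells of the marrow niche. The comparison asks how signalling in the niche cell relates to the transcripts of the blood progenitors, in a study of myeloid malignancies. Total counts were 18678599, 17191996 and 17597517 in mutant mice 1, 2 and 3, and 19530103, 15431235 and 19956774 in WT mice 1, 2 and 3. Between 13423 and 15102 genes had a count in a library. The library of mutant mouse 2 stood apart from the others on the first principal component, which held 50.8% of the variance. By Xist and Y-linked counts, mutant mice 1 and 2 were male, and mutant mouse 3 and the 3 WT mice were female. Xist itself had a log2 fold change of -1.69 ± 1.61 (SE).

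Transcripts of the granulocyte-monocyte lineage were higher in LSK cells of the mutant mice, and interferon-induced transcripts were lower, as lists at the preset correlation. The 2 lists had an adjusted p = 0.114 and adjusted p = 0.303 with an estimated correlation, and adjusted p = 0.0776 and adjusted p = 0.229 by fry. Mpo, the myeloperoxidase of neutrophil granules, averaged 5739.7 ± 1043 CPM in mutant and 1966 ± 819 CPM in WT mice (SD, n = 3 each). Isg15, an interferon-induced ubiquitin-like modifier, averaged 10.2 ± 4.73 CPM in mutant and 23.3 ± 6.28 CPM in WT mice. The B cell transcripts Cd79a and Ebf1 were below 4 CPM in mutant mice 2 and 3 and at 109 and 40.9 CPM in mutant mouse 1. No single gene passed the threshold over all 12653 genes tested. By edgeR's quasi-likelihood test 0 genes were higher and 0 lower at an adjusted p under 0.05, with 434 higher and 396 lower at an unadjusted p under 0.05. limma-voom gave 0 and 0, and DESeq2 gave 106 higher and 77 lower, with the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y among the 106. All 3 mutant values lay above all 3 WT values for 872 genes and below them for 970, together 14.6% of the genes tested, where chance gives 10% on average. Genes vary together, so the share in a single grouping can lie far from 10%, and the excess was not tested. An exact permutation test of 3 against 3 mice cannot go below 0.10.

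The 5 higher genes with the smallest unadjusted p were Hp, Id2, Emilin2, Klf9 and Igsf6. Hp, the haemoglobin-binding plasma protein haptoglobin, which is also stored in myeloid granules, lies on chromosome 8 from 109575128 to 109579172. Its log2 fold change was 2.99 ± 0.39 (SE), with 86.8 ± 35.3 CPM in mutant and 10.9 ± 3.82 CPM in WT mice (SD, n = 3 each). Id2, an inhibitor of helix-loop-helix transcription factors (chromosome 12, 25093799 to 25096092), had a log2 fold change of 2.04 ± 0.31. Emilin2, a matrix glycoprotein gene (chromosome 17, 71252172 to 71311556), had 2.45 ± 0.37, and Klf9, a glucocorticoid-responsive transcription factor gene (chromosome 19, 23141226 to 23168129), had 2.12 ± 0.32. Igsf6 (chromosome 7, 121064067 to 121074581) averaged 27.8 ± 0.79 CPM in mutant and 6.49 ± 2.37 CPM in WT mice. The edgeR adjusted p was 0.292 for each of these 5 genes, and all 3 mutant mice lay above all 3 WT mice in each.

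The 5 lower genes with the smallest unadjusted p were Cd5l, Fxyd6, Steap4, Ly6a and Retnlg. Cd5l, a secreted macrophage protein gene (chromosome 3, 87357881 to 87371074), had 0 counts in the 3 mutant libraries and 68, 41 and 49 counts in WT mice 1, 2 and 3, at least 16.0-fold lower against a floor of 3 counts per library. Fxyd6 (chromosome 9, 45369470 to 45396159) had 2 counts over the mutant libraries and 356 over the WT libraries, a ratio of 0.00577 (95% counting interval 0.000696 to 0.0210). Steap4 (chromosome 5, 7960472 to 7982213) had 1 and 149 counts, a ratio of 0.00689 (0.000173 to 0.0390). Retnlg, a neutrophil secreted protein gene (chromosome 16, 48872608 to 48874498), had 3 and 183 counts, a ratio of 0.0168 (0.00344 to 0.050). Ly6a encodes Sca-1, a surface protein by which LSK cells are sorted, and is interferon-inducible. It lies on chromosome 15 from 74994877 to 74998031 and averaged 74.4 ± 7.87 CPM in mutant and 155 ± 6.75 CPM in WT mice (SD, n = 3 each), a log2 fold change of -1.06 ± 0.18 with an edgeR adjusted p of 0.312. The adjusted p was 0.292 for Cd5l, Fxyd6 and Steap4 and 0.312 for Retnlg.

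Genes of granulocyte-monocyte progenitors were higher in mutant mice as a list. Of 20 tested members, 19 had a positive log2 fold change, the list median was 1.29, and the mutant mice lay above the WT mice without overlap for 15. The list, which also holds Hp, passed with a camera adjusted p of 1.71e-27 at the preset correlation, but not with an estimated one (adjusted p = 0.114 with an estimated correlation). Adjusted over the list alone, 15 members were higher and 0 lower by edgeR, while 0 passed over all genes tested. DESeq2 called 10 members higher and 0 lower over all genes. Cebpa, the transcription factor that directs progenitors to the granulocyte-monocyte fate, averaged 45.9 ± 5.42 CPM in mutant and 19.1 ± 0.68 CPM in WT mice (SD, n = 3 each). Ly6c2, a surface protein of monocytes and their progenitors, had a log2 fold change of 2.64 ± 0.48 (SE), and Fcgr3, an IgG receptor, one of 1.86 ± 0.35. The granule protease genes Elane (2.67 ± 0.55), Prtn3 (1.89 ± 0.50) and Ctsg (2.78 ± 0.78) and the myeloid gene Ms4a3 (3.59 ± 0.76) were also among the 15, as were the lineage transcription factors Irf8 (1.31 ± 0.40) and Gfi1 (0.59 ± 0.18). Csf3r, the receptor of granulocyte colony-stimulating factor, was the member with a negative value, -0.66 ± 0.32. In each mutant mouse the list median lay above that of each WT mouse: 1.55, 1.49 and 1.11 log2 units over the WT mean in mutant mice 1, 2 and 3.

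**Figure D1:**
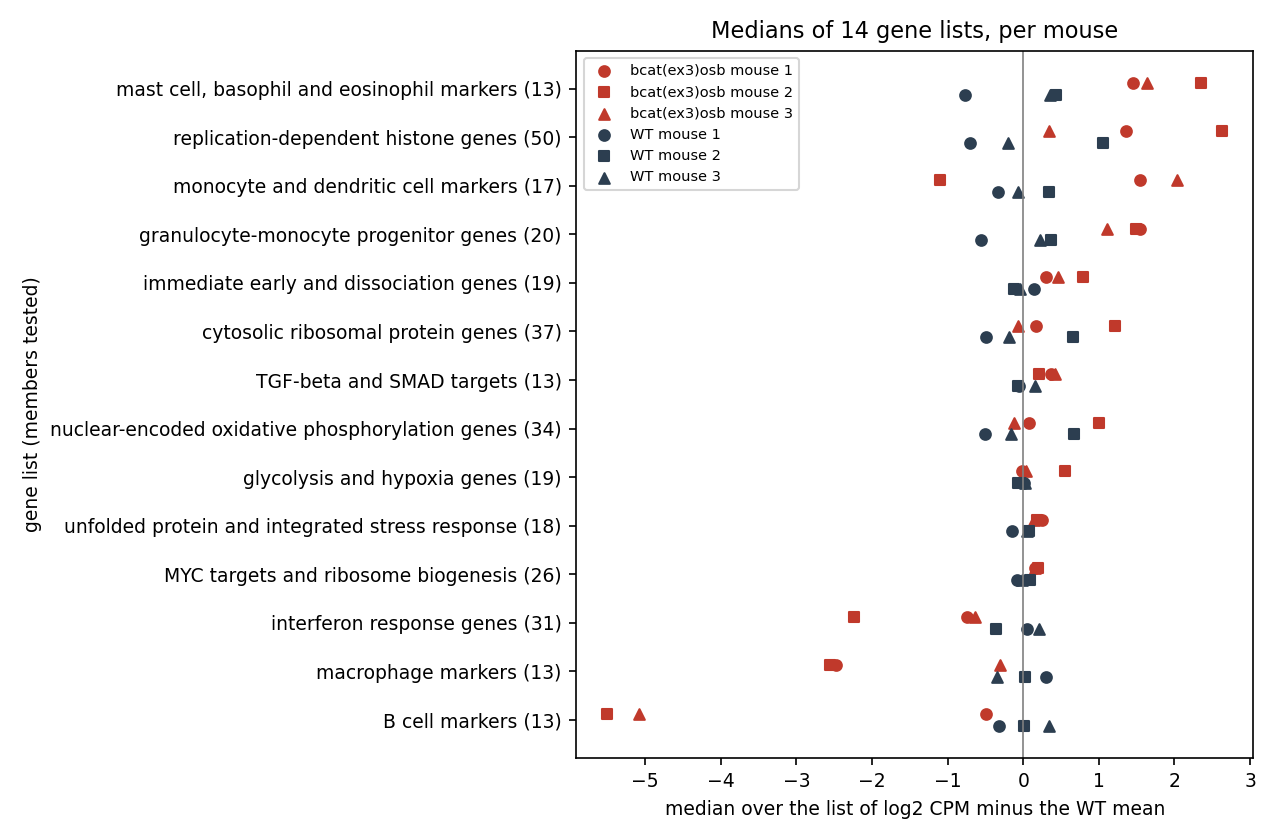
Median over each gene list of log2 CPM minus the WT mean (x axis, log2 units) for the 14 lists past the threshold at the preset correlation (y axis, with the number of members tested). Each point is 1 mouse, red for bcat(ex3)osb and dark for WT, with the mouse number as the symbol. For the granulocyte-monocyte list the 3 mutant mice sit at 1.55, 1.49 and 1.11, above the 3 WT mice, and for B cell markers mutant mice 2 and 3 sit at -5.50 and -5.09.

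Markers of monocytes and dendritic cells and of mast cells, basophils and eosinophils were higher as lists. Monocyte and dendritic cell markers had a list median of 1.53 over 17 genes, with 16 positive and 4 higher when adjusted over the list alone (camera adjusted p = 1.22e-07 at the preset correlation, adjusted p = 0.381 with an estimated correlation). The 4 were Ccr2, the receptor by which monocytes leave the marrow (35.2 ± 5.63 CPM in mutant and 8.08 ± 3.23 CPM in WT mice, SD, n = 3 each), F13a1, Ms4a6c and Itgax. The antigen presentation genes of this list differed between mutant mice: Cd74 was at 300.3, 66.2 and 1436 CPM in mutant mice 1, 2 and 3 and between 127 and 233 CPM in WT mice. The median of the list was 1.54, -1.10 and 2.04 in mutant mice 1, 2 and 3, relative to the WT mean. Without mutant mouse 3 the list median was 0.49, and on log2(FPKM + 1) it was 0.88. Mast cell, basophil and eosinophil markers had a list median of 1.95 over 13 genes, with 11 positive and 3 higher when adjusted over the list alone (camera adjusted p = 5.16e-06, adjusted p = 0.114 with an estimated correlation). These 3 were Cd200r3, Hdc, the histamine-forming enzyme (36.8 ± 13.1 against 8.65 ± 4.73 CPM), and Cpa3, a mast cell protease (104 ± 40.1 against 27.0 ± 16.6 CPM). Prg2, the eosinophil major basic protein, had a log2 fold change of 1.86 ± 0.74 and did not pass over the list. The mast cell list median was 1.02 with sex as a covariate, 1.21 in the 4 female mice, 0.98 by limma-voom and 1.28 on log2(FPKM + 1).

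Interferon response genes were lower in mutant mice as a list. All 31 tested members had a negative log2 fold change, with a median of -1.20, and for 24 of them the mutant mice lay below the WT mice without overlap. The camera adjusted p was 2.15e-22 at the preset correlation, and the call was lost with an estimated one (adjusted p = 0.303 with an estimated correlation). Adjusted over the list alone, 2 members were lower: Gbp2, an interferon-induced GTPase (27.0 ± 5.73 CPM in mutant and 64.2 ± 16.4 CPM in WT mice, SD, n = 3 each), and Zbp1, a nucleic acid sensor (4.47 ± 1.34 and 13.1 ± 2.84 CPM). Ifi27l2a and Ifit3 had log2 fold changes of -2.08 ± 0.55 and -3.07 ± 0.84, Isg15 -1.19 ± 0.42, and Irf7, a transcription factor of the response, -1.07 ± 0.46. The decrease was deepest in the library that stood apart: the list median was -0.75, -2.24 and -0.64 log2 units against the WT mean in mutant mice 1, 2 and 3. In WT mice 1, 2 and 3 the list median was 0.05, -0.36 and 0.21. Without mutant mouse 2 it was -0.77, with sex as a covariate -0.70 and in the 4 female mice -0.71.

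**Figure D2:**
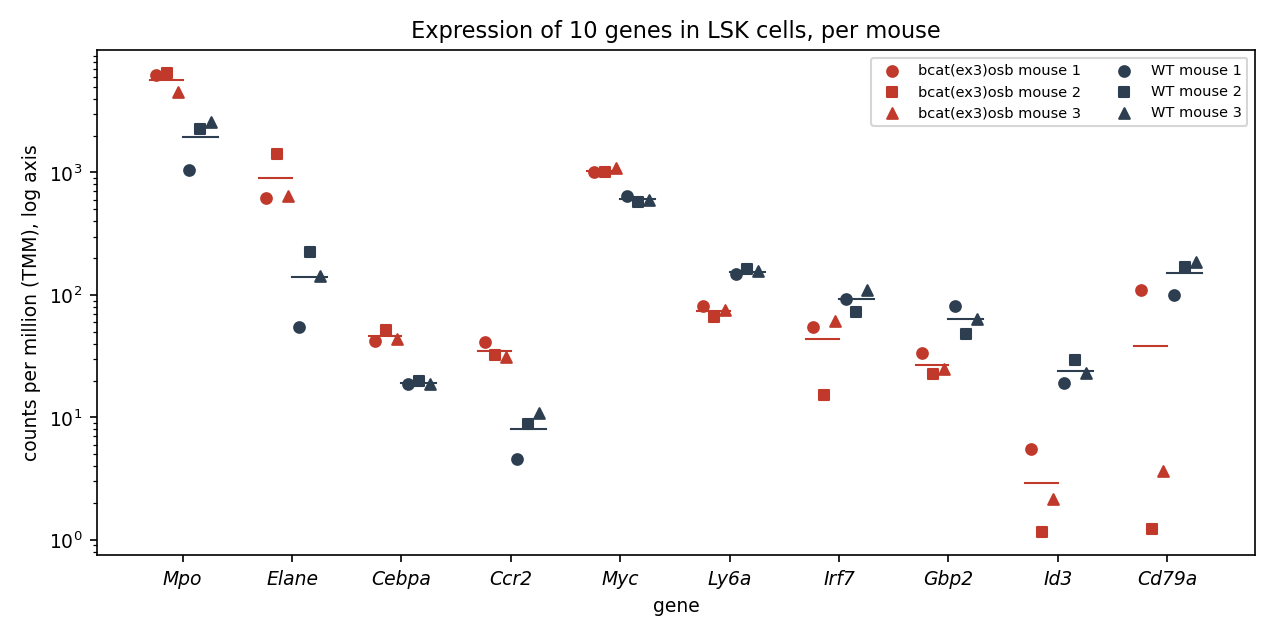
TMM-scaled CPM (log y axis) of 10 genes (x axis) in LSK cells. Each point is 1 mouse, red for bcat(ex3)osb and dark for WT, and horizontal lines are group means of 3 mice. Myc and Ly6a separate the groups with little spread, and Cd79a lies at 109, 1.23 and 3.66 CPM in mutant mice 1, 2 and 3 against 100.2 to 187 CPM in WT mice.

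B cell and macrophage markers were lower in mutant mice as lists. All 13 tested B cell markers had a negative log2 fold change, with a median of -1.96 (camera adjusted p = 1.75e-10, adjusted p = 0.303 with an estimated correlation), and 0 passed when adjusted over the list alone. The mutant mice differed among themselves: Cd79a, a signalling chain of the B cell receptor, was at 109, 1.23 and 3.66 CPM in mutant mice 1, 2 and 3 and at 100.2 to 187 CPM in WT mice. Ebf1, a transcription factor that specifies B cells, was at 40.9, 0.0645 and 0.665 CPM in mutant mice 1, 2 and 3, and at 33.9 to 58.9 CPM in WT mice. Cd79b, Bank1 and Vpreb3 had log2 fold changes of -0.64 ± 0.26, -1.07 ± 0.49 and -2.89 ± 1.33. Without mutant mouse 1 the list median was -5.74, and Vpreb3, Ebf1, Igll1, Vpreb1, Blnk, Cd79a and Pou2af1 were among the 13 genes that then passed as lower over all genes. The B cell list median was -5.20 with sex as a covariate, -5.21 in the 4 female mice, -3.65 by limma-voom and -2.96 on log2(FPKM + 1). The settings by sex rest on mutant mouse 3 alone for the genotype difference. Against the WT mean, the median was -0.49, -5.50 and -5.09 in mutant mice 1, 2 and 3 and -0.32 to 0.34 in WT mice. Macrophage markers had a median of -1.30 over 13 genes, also with Cd5l set at its bound, with 12 negative (camera adjusted p = 5.13e-08, adjusted p = 0.303 with an estimated correlation). Adjusted over the list alone, Cd5l was lower and Cd68, a lysosomal protein also made by other myeloid cells, was higher (62.2 ± 28.9 against 26.4 ± 1.90 CPM). Vcam1 and C1qb, a complement component, had log2 fold changes of -1.68 ± 0.57 and -2.01 ± 0.90. Against the WT mean, the macrophage list median was -2.48, -2.55 and -0.30 in mutant mice 1, 2 and 3. It was 0.29, 0.02 and -0.35 in WT mice 1, 2 and 3, so mutant mouse 3 lay within the WT range. The macrophage list median was -2.50 without mutant mouse 3, -0.55 with sex as a covariate and -0.64 in the 4 female mice.

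Myc, a transcription factor that drives growth, was higher in mutant mice with little spread: 1034 ± 39.4 CPM against 603 ± 34.8 CPM in WT mice (SD, n = 3 each), a log2 fold change of 0.78 ± 0.17 with an edgeR adjusted p of 0.333. It lies on chromosome 15 from 61985341 to 61990361. The list of MYC targets and ribosome biogenesis, of which Myc itself is a member, had a median of 0.14 over 26 genes, with 23 positive, and Myc was the 1 member higher when adjusted over the list alone. Ppan, Gar1 and Nolc1, which act in ribosome assembly, had log2 fold changes of 0.51 ± 0.18, 0.51 ± 0.29 and 0.31 ± 0.18. The camera adjusted p was 0.00700 at the preset correlation (adjusted p = 0.234 with an estimated correlation), and the call ended with sex as a covariate (0.14) and in the 4 female mice (0.12). On log2(FPKM + 1) the MYC median was 0.08. TGF-β and SMAD targets had a median of 0.36 over 13 genes (camera adjusted p = 0.0273, adjusted p = 0.303 with an estimated correlation). Within this list the helix-loop-helix inhibitors went apart when adjusted over the list alone: Id2 and Id1 (1.58 ± 0.46) were higher and Id3 (-3.01 ± 0.56; 2.94 ± 2.27 against 23.9 ± 5.39 CPM) was lower. Smad7, a feedback inhibitor of the pathway, was also higher (0.78 ± 0.25). The TGF-β call ended without mutant mouse 1 (median 0.37), mutant mouse 3 (0.17) or WT mouse 2 (0.20), and the median was 0.23 on log2(FPKM + 1).

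Immediate early genes, which respond within minutes to stimuli and to cell dissociation, had a median of 0.55 over 19 genes, with 14 positive and 6 higher when adjusted over the list alone. These were Junb, Fos, Zfp36, Egr1, Jun and Ier2. Junb averaged 158 ± 54.7 CPM in mutant and 65.8 ± 10.5 CPM in WT mice (SD, n = 3 each), and Fos 38.2 ± 41.6 and 2.58 ± 2.32 CPM. The camera adjusted p was 2.43e-06 (adjusted p = 0.114 with an estimated correlation). Without mutant mouse 2 the list median was 0.34.

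Histone, ribosomal protein and oxidative phosphorylation genes were higher as lists, and both the size and the calls changed with the libraries and settings used. Replication-dependent histone genes had a median of 1.57 over 50 genes, with 44 positive and 0 passing when adjusted over the list alone (camera adjusted p = 1.38e-14, adjusted p = 0.453 with an estimated correlation). Hist1h1a had a log2 fold change of 1.58 ± 0.37, Hist1h3e 2.12 ± 0.61, Hist1h3f 1.90 ± 0.70 and Hist1h4c 2.60 ± 0.96 by edgeR. DESeq2 called 2 histone genes higher over all genes, Hist1h1a and Hist1h3e, and 0 lower. The histone median was 1.00 on log2(FPKM + 1) and 0.71 without mutant mouse 2, and the call ended with sex as a covariate (0.16) and in the 4 female mice (0.13). Cytosolic ribosomal protein genes had a median of 0.45 over 37 genes, all positive, among them Rpl27, Rpl32, Rpl36 and Rpl38 at 0.74 ± 0.44, 0.67 ± 0.42, 0.80 ± 0.51 and 0.80 ± 0.54 (camera adjusted p = 7.32e-06, adjusted p = 0.693 with an estimated correlation). Their median was -0.03 without mutant mouse 2, 0.26 without WT mouse 1, 0.89 without WT mouse 2, 0.68 without mutant mouse 3, -0.16 with sex as a covariate and -0.18 in the 4 female mice. The call ended without mutant mouse 2, with sex as a covariate and in the 4 female mice. Nuclear-encoded oxidative phosphorylation genes had a median of 0.33 over 34 genes (camera adjusted p = 0.00532, adjusted p = 0.782 with an estimated correlation). Cox4i1, a subunit of cytochrome c oxidase, had a log2 fold change of 0.52 ± 0.43, Ndufv1 0.36 ± 0.25, Cycs 0.35 ± 0.27 and Ndufs1 -0.29 ± 0.20. The oxidative phosphorylation median was -0.11 without mutant mouse 2, 0.10 without WT mouse 1, 0.21 without WT mouse 3, 0.70 without WT mouse 2 and 0.52 without mutant mouse 3. It was -0.23 with sex as a covariate, -0.25 in the 4 female mice and 0.20 with the length and GC trend removed. The call ended in these 3 settings and without mutant mouse 2, WT mouse 1 or WT mouse 3.

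**Figure D3:**
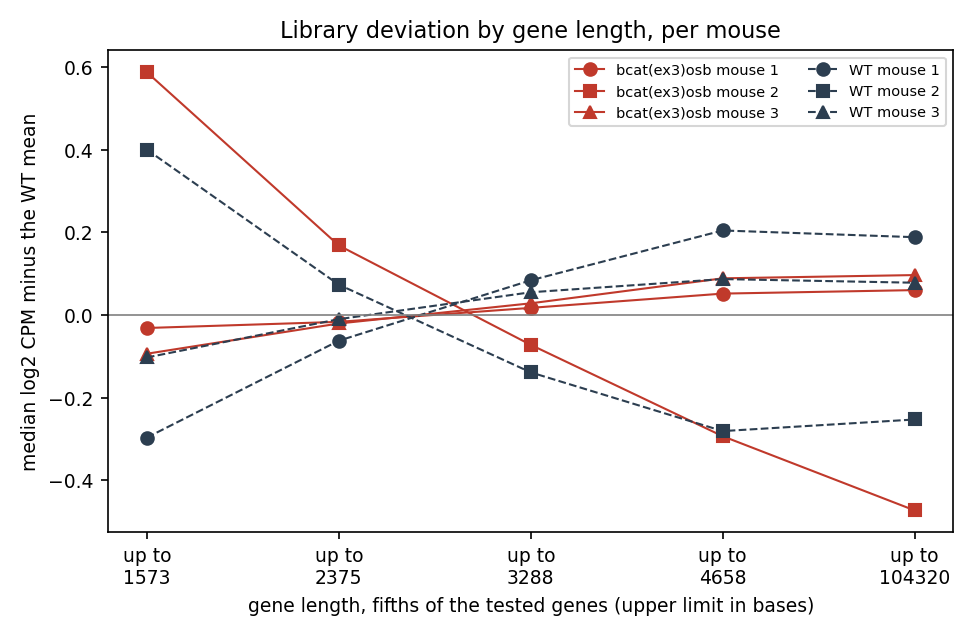
Median log2 CPM minus the WT mean (y axis) of the tested genes in 5 bins of gene length (x axis, upper limits in bases) for each mouse, red for bcat(ex3)osb and dark dashed for WT. Mutant mouse 2 and WT mouse 2 lie at 0.59 and 0.40 for genes up to 1573 bases and at -0.47 and -0.25 for the longest genes.

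Short genes took a larger share in the libraries of mutant mouse 2 and WT mouse 2. The tested genes had a median length of 2810 bases, the histone list 479, the ribosomal protein list 740, the granulocyte-monocyte list 1349 and the interferon list 2639. Ribosomal protein genes made up 5.47% of counts in mutant mouse 2 and 4.20% in WT mouse 2, and between 2.10% and 3.00% in the other 4 libraries. Rn45s, the ribosomal RNA precursor, took 1.01%, 1.21% and 0.652% of counts in mutant mice 1, 2 and 3 and 0.267%, 0.969% and 0.327% in WT mice 1, 2 and 3.

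Glycolysis and hypoxia genes had a median of 0.24 over 19 genes, with 15 positive and 0 passing when adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.453 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase, had a log2 fold change of 1.00 ± 0.29, Ldha, lactate dehydrogenase, 0.57 ± 0.23, Pgam1 0.54 ± 0.23 and P4ha1 -0.53 ± 0.24. The call ended without mutant mouse 2 (0.06), without WT mouse 2 (0.23), with sex as a covariate (0.02) and in the 4 female mice (0.00059). On log2(FPKM + 1) the glycolysis median was 0.14. Genes of the unfolded protein and integrated stress response had a median of 0.19 over 18 genes, with 13 positive (camera adjusted p = 0.0423, adjusted p = 0.569 with an estimated correlation). Asns, asparagine synthetase, had a log2 fold change of 0.60 ± 0.22, Herpud1 0.47 ± 0.18, Dnajb9 0.50 ± 0.22 and Manf 0.64 ± 0.30. That call ended without mutant mouse 1 (0.13), without WT mouse 1 (0.07), with upper-quartile factors (0.15), with sex as a covariate (0.13), in the 4 female mice (0.11) and with the length and GC trend removed (0.21). The mouse number as a block ended it too. On log2(FPKM + 1) the median was 0.09.

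Stem cell genes did not pass: the median was -0.21 over 30 genes, with 19 negative (camera adjusted p = 0.143), and 0 members passed when adjusted over the list alone. Procr, the surface protein EPCR of stem cells, averaged 24.7 ± 3.90 CPM in mutant and 38.1 ± 8.13 CPM in WT mice (SD, n = 3 each), Mllt3 28.0 ± 2.23 and 41.1 ± 7.97 CPM, Ifitm3 320 ± 44.8 and 460 ± 128 CPM, and Eya1 29.0 ± 1.91 and 42.4 ± 12.5 CPM. The stem cell list passed as lower without mutant mouse 2 (-0.30) or WT mouse 3 (-0.28), and had -0.05 without WT mouse 1. Kit, the other gene that defines the sort, had a log2 fold change of -0.39 ± 0.42 (chromosome 5, 75574987 to 75656722).

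Notch and Wnt transcripts were examined as lists fixed beforehand. The 7 tested Notch targets were all negative, with a median of -0.41, and did not pass (camera adjusted p = 0.116). Mutant and WT mice overlapped in all 7. Notch3 had a log2 fold change of -1.59 ± 0.78 and Dtx1 -1.69 ± 1.34, both at low levels. Notch3 averaged 0.596 CPM in mutant and 1.83 CPM in WT mice, and Dtx1 0.225 and 0.757 CPM. Hes5 had -0.41 ± 0.37 and Hes1 -0.66 ± 0.72 (chromosome 16, 30065357 to 30067796). Notch1 had -0.02 ± 0.32 (chromosome 2, 26457902 to 26503822), at 124 and 126 CPM. Nrarp had -0.05 ± 0.25, at 14.3 and 14.9 CPM, and Gata3 -0.05 ± 0.34, at 9.60 and 9.91 CPM. The Notch target list passed as lower without mutant mouse 1 (-0.71), mutant mouse 3 (-0.41) or WT mouse 2 (-0.25). Notch pathway components had a median of 0.04 over 21 genes (camera adjusted p = 0.420), with Ncstn at 0.48 ± 0.25, Aph1a at 0.35 ± 0.27 and Adam10 at -0.34 ± 0.37. Their median was -0.10 to 0.14 when each mouse was left out. Wnt/β-catenin targets had a median of 0.01 and a mean of -0.15 over 11 genes (camera adjusted p = 0.650), and medians of -0.19 to 0.26 when each mouse was left out. Within the Wnt list Lef1 was at 20.7, 0.194 and 1.94 CPM in mutant mice 1, 2 and 3 and between 33.4 and 86.6 CPM in WT mice. Tcf7l2 had a log2 fold change of -0.51 ± 0.21, Nkd1 1.10 ± 0.45 and Ccnd1, cyclin D1, 1.09 ± 0.47. Ctnnb1, the β-catenin gene (chromosome 9, 120933400 to 120960507), averaged 303 ± 33.5 CPM in mutant and 384 ± 109 CPM in WT mice (SD, n = 3 each). The activating change was placed in osteoblasts, so Ctnnb1 in LSK cells does not check the labels. Jag1 and Axin2 had too few counts to be tested, at most 21 counts for Jag1 and 12 for Axin2 in a library.

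Other lineage and cell state lists did not pass. Mature neutrophil markers had a median of 0.11 over 16 genes (camera adjusted p = 0.293), and adjusted over the list alone 3 were higher (Fcnb, Cxcr2 and S100a8) and 2 lower (Retnlg and Padi4). Fcnb averaged 9.54 ± 2.53 CPM in mutant and 2.44 ± 0.62 CPM in WT mice, and Padi4, a histone-modifying enzyme, 53.7 ± 4.78 and 99.2 ± 35.9 CPM (SD, n = 3 each). Without WT mouse 1 the neutrophil list passed as higher, with a median of 1.43, as it did with sex as a covariate (0.47) and in the 4 female mice (0.45), and the median was -0.21 without WT mouse 2 and -0.11 without WT mouse 3. Lymphoid-primed progenitor genes had a median of -0.31 over 14 genes (camera adjusted p = 0.402), with Cd53 at 0.62 ± 0.22, Mn1 at -0.40 ± 0.19 and Il12a at -0.44 ± 0.25, and passed as lower without mutant mouse 1 (-0.38; -0.20 without mutant mouse 3, where it did not pass), with sex as a covariate (-0.35) and in the 4 female mice (-0.37). The lymphoid-primed list had 6 positive and 8 negative members. Among the negative ones, Rag1 was at 28.2, 0.129 and 0.61 CPM in mutant mice 1, 2 and 3 (WT 11.0 to 22.2). Rag2 was at 54.2, 3.16 and 8.43 CPM (WT 38.6 to 61.6), and Il7r at 44.0, 4.65 and 7.98 CPM (WT 23.2 to 47.3). Dntt was at 1170, 176 and 365 CPM (WT 736 to 1183). Megakaryocyte genes had a median of 0.14 over 14 genes (camera adjusted p = 0.112). Adjusted over the list alone, 2 were higher: Itga2b, the integrin CD41 (89.6 ± 40.6 against 26.6 ± 6.59 CPM), and Selp, P-selectin (27.1 ± 9.71 against 9.67 ± 0.36 CPM). The megakaryocyte list passed as higher without mutant mouse 1 (0.26) or WT mouse 1 (0.44), with sex as a covariate (0.62) and in the 4 female mice (0.35), and turned to -0.19 without mutant mouse 3 and to -0.13 without WT mouse 2. Erythroid genes had a median of 0.04 and a mean of -0.08 over 13 genes (camera adjusted p = 0.783), with Tfrc, the transferrin receptor, at 0.81 ± 0.32. Leaving out each mouse in turn gave erythroid medians of -0.14 to 0.46. S phase genes had a median of 0.05 over 28 genes (camera adjusted p = 0.561), G2M phase genes -0.13 over 30 genes (0.174) and quiescence genes and cell cycle inhibitors -0.24 over 14 genes (0.154), with Tob1, an inhibitor of proliferation, at -0.83 ± 0.27. G2M phase genes passed as lower without mutant mouse 1 (-0.29) or WT mouse 1 (-0.24), and had 0.01 without mutant mouse 3 and -0.02 without WT mouse 2. With sex as a covariate and in the 4 female mice, G2M genes (-0.47 and -0.49) and quiescence genes (-0.32 and -0.34) passed as lower. Leukaemia-associated regulators had a median of 0.00099 and a mean of -0.02 over 23 genes (camera adjusted p = 0.923), with Bcl2, an inhibitor of apoptosis, at 0.55 ± 0.23. Leaving out each mouse in turn gave medians of -0.07 to 0.10 for these regulators, -0.01 to 0.06 for S phase genes and -0.32 to -0.19 for quiescence genes.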

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

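No test in this part was chosen after the result was seen. Y-linked genes were outside the edgeR comparison of all 6 mice, since the filter on low counts removed them, and they gave a clear signal in some mutant libraries. Levels of Y-linked genes are given here relative to the library's total counts, without TMM scaling. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together were at 199 CPM in bcat(ex3)osb mouse 1 and at 165 in bcat(ex3)osb mouse 2, above the WT level of at most 0.666. In bcat(ex3)osb mouse 3 they were at 0.682 CPM. DESeq2 called all 4 higher. Xist, the transcript of the inactive X chromosome, had 24 and 10 counts in mutant mice 1 and 2, and between 2517 and 5110 counts in mutant mouse 3 and the 3 WT mice. By these counts mutant mice 1 and 2 were male, and mutant mouse 3 and all 3 WT mice were female. Groups of 3 mice are too small for a test of single outlying mice.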

How the results depend on the processing

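The settings with sex as a covariate, with the 4 female mice and with the length and GC trend removed were chosen after seeing the data. The planned sex covariate was to run only if both groups held both sexes; the WT group held only females, so it was not run as planned. With the 4 female mice the lone mutant mouse 3 is assumed to vary like the others. With sex as a covariate the genotype difference also rests on mutant mouse 3, the only female mutant mouse. The counts of 0 genes higher and 0 lower were the same under RLE and upper-quartile factors, limma-voom, both filters on low counts, both FPKM settings, an adjusted p under 0.10, the robust fit, sex as a covariate and the 4 female mice. DESeq2 called 106 higher and 77 lower. Of these 183 genes, 171 were tested by edgeR, and all 171 had an unadjusted edgeR p under 0.05 and the same sign. Both tools used the same counts and groups, so this overlap is not independent support. With the length and GC trend removed 1 gene was higher, Hp. Leaving out each mouse in turn gave 0 to 4 genes higher and 0 to 13 lower, and 8 to 12 lists higher and 3 to 8 lower. Without mutant mouse 1 it was 1 higher and 13 lower and 8 lists lower; without mutant mouse 3, 4 higher, all Y-linked, and 2 lower, Xist and Gria2; without WT mouse 2, 6 lists were lower. Against 11 lists higher and 3 lower as reported, camera with an estimated correlation called 0 and 0, fry 0 and 0, sex as a covariate 7 and 6, and the 4 female mice 7 and 7. Oxidative phosphorylation genes had -0.11 to 0.70 when each mouse was left out, reversed at -0.11 without mutant mouse 2, and reversed to -0.23 with sex as a covariate and to -0.25 in the 4 female mice. Ribosomal protein genes reversed to -0.16 with sex as a covariate and to -0.18 in the 4 female mice. The cause was not tested. Over all lists and settings, 440 values kept their direction and side of the threshold, 50 lost the call, 26 gained it, 39 uncalled ones changed direction and 5 reversed. The 5 were of ribosomal protein (2) and oxidative phosphorylation (3) genes. They changed direction and also lost their call, and were not called lower. Direction here is that of camera, which can differ from the sign of the median: the ribosomal protein median of -0.03 without mutant mouse 2 counts as a lost call. For the named genes, 3396 values were the same, 60 gained a call and 26 uncalled ones changed sign. All settings left the median of all genes within 0.0938 log2 units of 0.

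With the mouse number as a replicate block, 5 genes were higher (Elane, Ms4a3, Klf9, Mt1 and Hp) and 0 lower, against 0 and 0 without it, and 10 lists were higher and 3 lower, since the unfolded protein list lost its call (0.17). The numbers were not treated as pairs: deviations of same-numbered mice correlated at 0.110, 0.344 and 0.0567 for numbers 1, 2 and 3 across genes. Not every mouse correlated best with its own number: mutant mouse 1 did so with WT mouse 3 (0.131) and mutant mouse 3 with WT mouse 1 (0.279). The spread between mice was a biological coefficient of variation of 0.349, and whether depth or spread limited the calls was not tested.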

Other observations

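The tests of sex, of mutant mouse 2 alone and of committed progenitors for the granulocyte-monocyte genes, the dilution test for the interferon genes, and the settings with sex as a covariate, the 4 female mice and the length and GC trend removed were chosen after results were seen. The reading that a single female mutant mouse leaves sex open was also settled after its values were seen. The lists of stromal and osteoblast, endothelial, and T and NK cell markers did not pass. Stromal and osteoblast markers had a median of -0.34 over 8 tested genes (camera adjusted p = 0.0825), but Postn, the matrix protein periostin, was lower when adjusted over the list alone, with 2.92 ± 0.75 CPM in mutant and 18.9 ± 10.3 CPM in WT mice (SD, n = 3 each). Alpl, the alkaline phosphatase of osteoblasts, was at 2.35 ± 2.24 and 14.8 ± 8.13 CPM, Pdgfrb at 113 ± 31.9 and 60.6 ± 23.7 CPM, and Runx2 at 116 ± 29.6 and 89.3 ± 17.3 CPM. Without mutant mouse 1 (-1.95) or WT mouse 2 (-0.77) this list passed as lower, and without mutant mouse 2 its median was 0.08. Endothelial markers had a median of -0.22 over 10 genes (camera adjusted p = 0.102), with Tie1 at -1.22 ± 0.37, Emcn at -1.16 ± 0.36, Eng at -0.52 ± 0.24 and Plvap at -0.67 ± 0.41, and passed as lower without mutant mouse 1 (-0.81) and in the 4 female mice (-0.59). Its median was 0.21 without mutant mouse 3 and 0.14 without WT mouse 1. T and NK cell markers had a median of -0.40 over 8 genes (camera adjusted p = 0.402), and -0.56 to -0.04 when each mouse was left out.

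Among the remaining pathways, p53 targets had a median of -0.35 over 19 genes (camera adjusted p = 0.143), with Pmaip1, the cell death protein NOXA, at 9.05 ± 2.09 CPM in mutant and 1.94 ± 1.31 CPM in WT mice, and Ddit4l at -3.10 ± 0.99, Sesn1 at -0.59 ± 0.23 and Plk2 at -2.28 ± 1.02 on the log2 scale. NF-κB and cytokine genes had a median of -0.04 and a mean of 0.01 over 17 genes (camera adjusted p = 0.985), DNA repair and Fanconi genes -0.06 over 22 (0.402), cholesterol and fatty acid synthesis genes -0.12 over 19 (0.199) and antioxidant and NRF2 genes 0.09 over 18 (0.402). Small and nuclear noncoding RNAs had a median of -0.04 and a mean of 0.02 over 8 (0.980), with Malat1 at 1019.9 ± 470 CPM in mutant and 1809 ± 802 CPM in WT mice. The cholesterol list passed as lower without WT mouse 2 (-0.32), and had 0.04 without WT mouse 3. When each mouse was left out, the medians were -0.46 to -0.12 for p53 targets, -0.14 to 0.06 for NF-κB genes, -0.15 to 0.06 for DNA repair genes, -0.18 to 0.26 for antioxidant genes and -0.36 to 0.56 for the noncoding RNAs. The mast cell protease genes differed between mutant mice: Tpsb2 was at 0.323, 25.4 and 96.9 CPM in mutant mice 1, 2 and 3 and between 4.09 and 5.63 CPM in WT mice, and Cma1 at 0.108, 17.5 and 43.9 CPM against 2.14 to 3.06 CPM. Mt1, a metallothionein, was at 20.5, 229 and 31.5 CPM in mutant mice 1, 2 and 3 and between 2.47 and 8.84 CPM in WT mice.

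The rise of granulocyte-monocyte progenitor genes was not carried by the library of mutant mouse 2 alone: without it the list median was 1.24. Mutant mice 1 and 3 had medians of 1.55 and 1.11 against the WT mean, and WT mice -0.56 to 0.36. The camera call at the preset correlation held too. It carries little weight, since the preset was 0.01 and the estimated correlation 0.31. Sex stays open, since 2 of the 3 mutant mice were male and no WT mouse was. The call held with sex as a covariate (1.03) and in the 4 female mice (1.01), and the female mutant mouse 3 had a list median 1.11 log2 units above the WT mean, with 16 of 20 members above every WT mouse. All 3 values rest on the single library of mutant mouse 3, which cannot exclude sex. Committed progenitors inside the sorted gate cannot be told apart from a shift within LSK cells: the stem cell list had a median of -0.21, with a 95% bootstrap interval over genes of -0.39 to 0.05. The gate selects for Sca-1, which committed granulocyte-monocyte progenitors lack, but sort purity is not in these files. Ly6a, which encodes Sca-1, was at 81.5, 65.9 and 75.7 CPM in mutant mice 1, 2 and 3 and between 148 and 162 CPM in WT mice. The genotype that the design names, active β-catenin signalling in osteoblasts, stays among the open explanations, as untested.

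Lower interferon response genes did not rest on mutant mouse 2 alone: without it the list median was -0.77. Mutant mice 1 and 3 had medians of -0.75 and -0.64 against the WT mean, and WT mice -0.36 to 0.21. The camera call at the preset correlation held too. That call carries little weight, since the preset was 0.01 and the estimated correlation 0.62. Dilution by cells that lack both interferon response and stem cell transcripts would lower both lists alike, and stays open. The stem cell list median lay 0.99 log2 units above the interferon list (95% bootstrap interval over genes 0.66 to 1.29), but 0.47 without mutant mouse 2, and that interval treats genes as independent and leaves out the spread between mice. Per mouse, against the WT mean, the gap was 0.34, 2.15 and 0.55 in mutant mice 1, 2 and 3 and -0.35 to 0.34 in WT mice. The bound on the spread between mice was set after these values were seen. Sex stays open: the female mutant mouse 3 had a list median of -0.64, with 26 of 31 members below every WT mouse, and the call held with sex as a covariate (-0.70) and in the 4 female mice (-0.71). The value of mutant mouse 3 met the bound set before the result was seen, but the bound was wrong in resting on a single library of that sex. Genotype may be the source of the difference, as a hypothesis untested against sex and dilution.

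Higher histone genes rested on the library of mutant mouse 2 for a large part of their size, but the excess was not confined to it. The list median against the WT mean was 1.36, 2.63 and 0.34 in mutant mice 1, 2 and 3 and 1.06 in WT mouse 2. Histone genes took 0.0909%, 0.116% and 0.0937% of counts in mutant mice 1 and 2 and WT mouse 2, and 0.0349% to 0.0451% in the other 3. Rn45s, a ribosomal RNA precursor, took 1.01%, 1.21% and 0.969% in the same 3 mice and 0.267% to 0.652% in the others. Without mutant mouse 2 the list median was 0.71, under the bound set beforehand, 0.5 of the 1.57 with all 6 mice, although the camera call held. After each library's trend with gene length and GC content was removed, the median was 1.24 and the call at the preset correlation held. That met the bound set beforehand against such a trend as the whole cause. The trend was fitted over all tested genes, and the histone genes, with a median length of 479 against 2810 bases, lie at its short end. A bias particular to very short genes therefore stays open, and the estimated correlation of the list was 0.67. Ribosomal protein genes had a median of -0.03 without mutant mouse 2. Sex as a covariate ended both calls, but that fit rests on mutant mouse 3 as the lone female mutant mouse. The female WT mouse 2 also had the excess. Ribosomal protein medians against the WT mean were 0.17 and 1.22 in the male mutant mice 1 and 2 and 0.66 in WT mouse 2. They were -0.49 to -0.08 in the other female mice. Sex remains open, and no biological explanation was tested.

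The 6 mice make 10 splits into 3 and 3, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 830 genes and the highest of the other splits 2097, and 4 of the 10 splits gave as many as the real one, which is among them. Past the adjusted threshold the real split gave 0 genes and the highest other 2. A count of 0 is met by 10 of the 10 splits whatever the data, so this count carries no information. For lists the real split gave 14 and the highest other 14, and 2 of the 10 splits gave as many. The split with 2097 genes set mutant mice 1 and 2 and WT mouse 2 against mutant mouse 3 and WT mice 1 and 3, and points to a structure of the samples other than genotype. The granulocyte-monocyte median was 1.29 in the real split and at most 0.82 in size in the others, and the interferon median -1.20 against at most 0.86 in size. These 2 lists had the smallest camera p-values in the real split, and each other split mixes mutant and WT mice in both groups. Their larger size in the real split is therefore no independent support for genotype.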
